A study of Mus musculus with 6 samples.

How the data were processed

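Total RNA of whole soleus muscles of male mice was extracted from cryostat sections, amplified with biotin labelling and hybridised to a mouse whole-genome Illumina beadchip, per the labels' protocols. The 6 samples, 3 per genotype, were placed in their groups by the sample titles, and both groups carry one strain designation (CBB6F1xFVB/n). The deposited scanner table was exported with BeadStudio 3.2.6 and holds intensity values without normalization between arrays, per the file headers. It has 1 row per gene target, the spread and number of beads behind each value, and a detection score per array that is 1 minus the detection p-value. In each array between 30.1% and 32.9% of the deposited intensity values lie at or below 0, which shows that a background level was subtracted before deposit. The authors also deposited a value table of 46632 probes, which fits a log2 scale with array medians between 7.75 and 7.76. The submitters' processing notes name BeadStudio and limma, and the normalization behind the value table is not given in the sources used here. Its rows carry probe identifiers that nothing used here pairs with genes, so only counts of probes were taken from it.

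Because the intensities were already background-subtracted, a constant of 42.7 was added to all values so that the lowest was 1, then an offset of 16, and the sums were put on the log2 scale and quantile normalized between arrays. The planned background model was kept for tables with no background removed, as fixed before the data were examined. The 58.7 units added in total understate the fold changes of dim genes. Rows with a detection p under 0.05 on at least 3 of the 6 arrays were tested, which left 12611 rows. Row names were updated with a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Of the 34492 rows, 22815 matched, 16339 by their own symbol and 6476 by a synonym of 1 gene, and the others kept the deposited name. A gene with several detected rows was stood for by the brightest, giving 12135 genes. A gene on no array of a group above background has only a bound: its bright group was set against the higher of its own signal and the lowest detected signal on each dim array, and the ratio is given as "at least".

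Genotypes were compared with limma 3.58.1 in R 4.3.3 (a linear model on genotype with moderated variances), with Benjamini-Hochberg adjustment and a threshold of 0.05. The actins and myosins were also compared with an exact permutation test. The replicate numbers name different mice, so they were not used as a block. The 24 gene lists, 8 of them markers of cell types that a whole muscle can hold, were fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 24 lists. The p-values of single members were also adjusted over their own list alone, with no correction over the 24 lists. Genes named in the text followed a rule fixed beforehand: the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between groups, all actins, 4 myosin heavy chains, up to 4 members of lowest p of each list, and changed genes within 20 Mb of Acta1. Provisional and clone names were counted and passed over.

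The procedure was tested on simulated data with 12611 rows and 200 changed rows in each of 20 simulations. It recovered 5.15% of log2 changes of 0.5, 75% of changes of 1 and 99.2% of changes of 2, and 6.40% of its calls were false. Changes of 0.5 are therefore mostly not detectable with these 6 arrays, and sizes between 0.5 and 1 were not simulated. In the data 18 rows passed. The adjustment is stricter where fewer rows change, so the recovered shares may be too high for these data. Lists shifted by 0.5 were found in 20 of 20 simulations by camera with the preset correlation, in 18 with an estimated correlation and in 19 with fry, but the simulated genes were independent of each other. Alternatives covered the normalization, the offset, the filter on dim rows, the variance model, array weights, the replicate number as a block, the position on the chip, the rows that stand for a gene, the threshold and each array left out in turn.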

Results

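RNA of the soleus, a postural hindlimb muscle rich in slow fibres, was profiled in male mice of 2 genotypes at 11 months of age. In 1 genotype, labelled Coco/KO and called cardiac actin mice here, skeletal muscle alpha-actin (Acta1) was knocked out and cardiac actin, the form of the heart and of fetal skeletal muscle, took its place, per the series title. The other genotype was wild type. Each genotype was represented by 3 RNA samples, each a pool of the RNA of 2 soleus muscles from different mice, and all 6 samples were hybridised to 1 Illumina beadchip. P-values therefore measure the spread between pools. Each array held 34492 rows with a median of 35 or 36 beads behind a value, and between 11606 rows (33.6%) and 13071 rows (37.9%) were detected above background. The mean intensity per array lay between 330.2 and 470.2, and correlations between arrays over the detected rows ranged from 0.968 to 0.983. The cardiac actin 1 array stood apart, with the lowest mean correlation to the others (0.970) and the highest score on the first principal component (34.4, against values from -15.5 to 5.48 on the other arrays). With 3 arrays per group, the number of arrays limits the precision of each comparison.

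The exchanged actins were examined first, because they check the labels. Acta1, the main sarcomeric actin of adult skeletal muscle, fell by 4.59 on the log2 scale (SE 0.20, n = 3 per group) in cardiac actin soleus, a 24.1-fold lower signal (limma, adjusted p = 2.79e-05). Its normalized log2 signal was 15.46 ± 0.17 (SD, n = 3) in wild type and 10.86 ± 0.34 in cardiac actin muscle, and its mean intensity went from 44608 to 1863. Actc1, cardiac alpha-actin, rose by 2.44 (SE 0.31), a 5.44-fold higher signal (limma, adjusted p = 0.0283), from 10.02 ± 0.58 to 12.46 ± 0.40 (SD, n = 3). Both genes separated the genotypes on all 6 arrays. The exact two-sided permutation test gave p = 0.1 for each, the smallest value that 3 arrays against 3 allow. Which part of the Acta1 transcript the array row measures, and whether the Actc1 row sees the cardiac actin that was brought in, is not given in the sources used here. The call for Actc1 was lost in 9 of 19 alternative settings, with adjusted p-values from 0.00980 to 0.355, while its direction was kept in all 19. Without wild-type array 1, 2 or 3 its adjusted p was 0.0694, 0.0624 and 0.0610, and without cardiac actin array 2 or 3 it was 0.0893 and 0.0869. Among the other actins, Acta2 of smooth muscle (log2 -0.23, SE 0.18), Actg2 of smooth muscle (-0.58, SE 0.26) and cytoplasmic Actb (-0.46, SE 0.21) did not pass the threshold. Over the alternatives Acta2 ranged from -0.40 to -0.13, Actg2 from -0.85 to -0.12 and Actb from -0.63 to -0.24. Of the 5 actin isoforms tested, 1 rose and 1 fell, over all genes and adjusted over the list alone. The list holds the knocked-out gene, so its camera result (direction down, adjusted p = 0.0498) is largely set by the genotype and says nothing about the other actins. The adjusted p was 0.626 with an estimated correlation. The camera call of the actin list was lost without wild-type array 1 (adjusted p = 0.140) or 2 (0.0751) and without cardiac actin array 1 (0.0673) or 3 (0.0611).

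**Figure D1:**
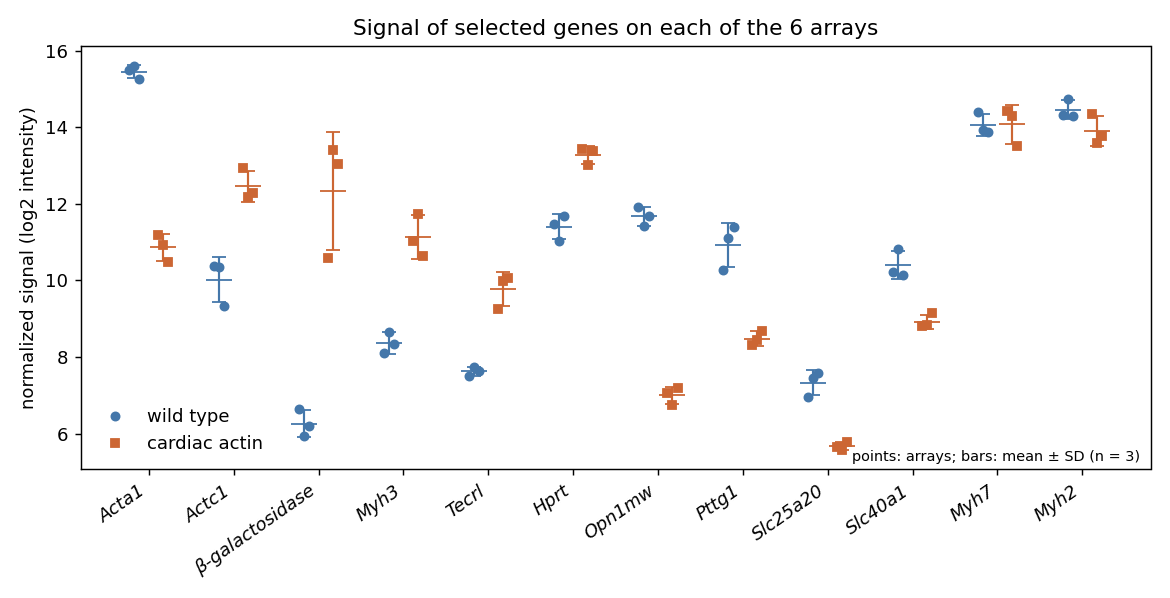
Normalized log2 intensity of 12 genes on each of the 6 arrays, with wild-type arrays as blue circles, cardiac actin arrays as orange squares, and the mean ± SD of the 3 arrays per group as bars. The Acta1 means are 15.46 and 10.86 and the Actc1 means 10.02 and 12.46, while the 2 groups of Myh7 arrays overlap.

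The comparison then asked which other transcripts differed between soleus with cardiac actin and wild-type soleus. Of 12135 genes tested, 18 passed an adjusted p of 0.05 in limma, 8 higher and 10 lower in cardiac actin muscle. Among these 18, in the main processing and in each alternative that gave it a value, the largest rise was on the array's row for β-galactosidase, a bacterial reporter enzyme with no mouse gene. Its log2 signal was 12.34 ± 1.53 (SD, n = 3) in cardiac actin and 6.26 ± 0.35 in wild-type muscle, a difference of 6.08 (SE 0.63, adjusted p = 0.0117), and 1 of the 3 wild-type arrays detected it. With wild-type signal near background, the 58.7 units added before the log2 step largely set the size of this difference, which was 5.56 with an offset of 50. It was 4.74 with background modelled from detection p-values, an alternative chosen after the data were seen and fitted to intensities already background-subtracted. The difference ranged from 5.60 to 6.96 with 1 array left out. Of those 6 sets only the one without cardiac actin array 1 (6.96) kept the call, and the adjusted p was 0.0587, 0.0546 and 0.0610 without wild-type array 1, 2 or 3 and 0.0512 and 0.0597 without cardiac actin array 2 or 3. Myh3, embryonic myosin heavy chain, rose by 2.77 (SE 0.28), a 6.83-fold higher signal (adjusted p = 0.0117). Tecrl, an endoplasmic reticulum enzyme of heart and skeletal muscle, rose by 2.14 (SE 0.22, adjusted p = 0.0117), and Hprt, the purine salvage enzyme hypoxanthine phosphoribosyltransferase, rose by 1.88 (SE 0.20, adjusted p = 0.0144). Smaller rises were found for Dct, a melanin synthesis enzyme (1.36, SE 0.19, adjusted p = 0.0463), and for Exosc9, a subunit of the RNA exosome. Dct was detected on 1 of the 3 wild-type arrays. Exosc9 was detected on none of them, and its signal was at least 1.96-fold higher in cardiac actin muscle (adjusted p = 0.0150). With modelled background the log2 changes shrank to 0.21 for Dct and 0.13 for Exosc9, below the bound given, and neither was called. The eighth gene that rose has a clone name (1.21, SE 0.17, adjusted p = 0.0463).

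Opn1mw, the medium-wavelength cone opsin gene on the X chromosome, fell about as far as Acta1, with a log2 change of -4.68 (SE 0.18), a 25.7-fold lower signal (limma, adjusted p = 2.44e-05). Which of these genes fell further depended on the setting, since modelled background gave -3.99 for Opn1mw and -4.86 for Acta1. Its mean intensity was 3202 in wild-type and 72.9 in cardiac actin muscle. Pttg1, securin of the cell cycle, fell by 2.44 (SE 0.27, adjusted p = 0.0150). Slc25a20, the mitochondrial carnitine and acylcarnitine carrier, was detected on all 3 wild-type arrays and on none of the cardiac actin arrays, an at least 2.43-fold lower signal (adjusted p = 0.0150). Its log2 change ranged from -1.88 to -0.20 over the alternatives, with the smallest change, under the bound given, from modelled background. Its call was lost without wild-type array 2 or 3 (adjusted p = 0.0775 and 0.0828) and without cardiac actin array 2 or 3 (0.0890 and 0.0597). Slc40a1, the iron exporter ferroportin, fell by 1.47 (SE 0.21, adjusted p = 0.0463), Tspan8, a tetraspanin, by 1.26 (SE 0.15, adjusted p = 0.0167) and Fam131a by 1.11 (SE 0.15, adjusted p = 0.0463). The other 3 genes that fell carry provisional or clone names and had log2 changes of -2.82, -2.65 and -2.58, which became -1.21, -0.96 and -2.50 with modelled background, where none of the 3 was called. All 18 genes had no overlap between the 3 arrays of one genotype and the 3 of the other; over all tested genes 1546 (12.7%) had none, where chance gives 10%. The calls depended on the arrays and on the processing. Without wild-type array 1, 2 or 3 there were 7, 9 and 6 genes, and without cardiac actin array 1, 2 or 3 there were 29, 7 and 5. Acta1 and Opn1mw were called in all 19 alternatives and were the only 2 genes left with modelled background. Not every call lost there went with a smaller change. Myh3 (2.95), Hprt (2.02) and Pttg1 (-2.64), for example, changed more than in the main processing (limma, adjusted p = 0.327, 0.327 and 0.355). Other changes, such as those of Dct, Exosc9 and Slc25a20, shrank. Which part of that model cost the calls was not tested. Myh3 was called in 16 of 19, Hprt in 14, Pttg1 and Tecrl in 13, Actc1 and Tspan8 in 10, Fam131a and the clone-named gene that rose in 6, and Slc40a1 in 4. Of the 18 alternatives that gave them a value, the β-galactosidase row was called in 12, Slc25a20 in 11, Exosc9 in 10 and Dct in 6. The other 3 genes that fell, in the order of the log2 changes given above, were called in 10 of 17, 16 of 18 and 17 of 19. Modelled background took Tspan8 from -1.26 to -0.27, although its row was detected on all 3 arrays of each genotype. Its mean intensities were 192.5 in wild-type and 44.1 in cardiac actin muscle.

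**Figure D2:**
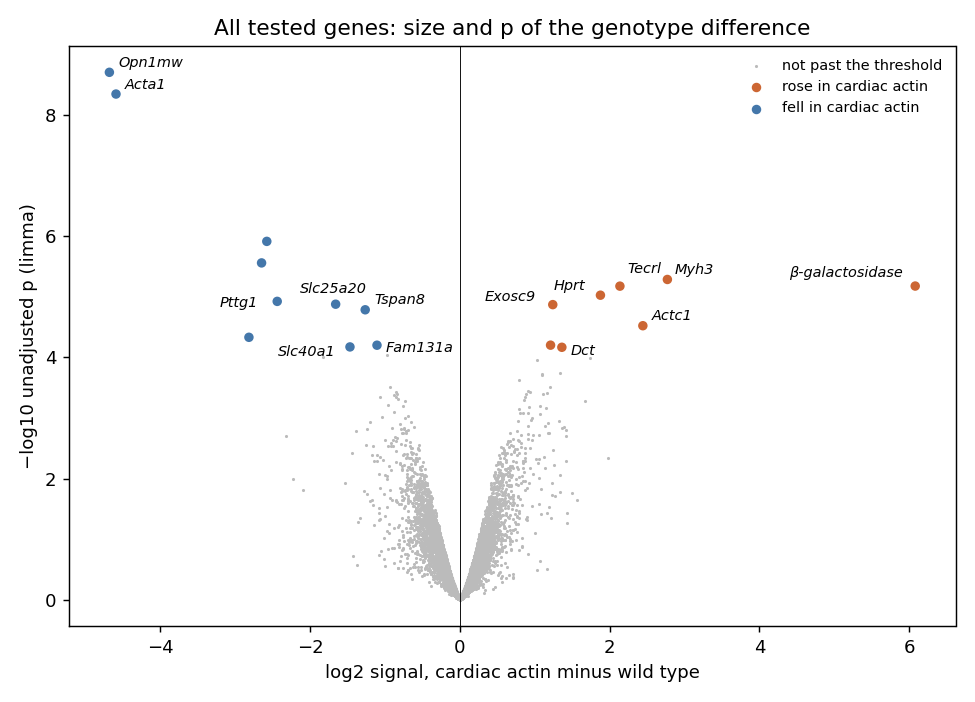
Log2 difference between cardiac actin and wild-type soleus (x axis) and the unadjusted limma p on a −log10 scale (y axis) for each of the 12135 genes tested, with the 8 genes that rose in orange, the 10 that fell in blue and genes that did not pass an adjusted p of 0.05 in grey. Opn1mw and Acta1 lie apart from the rest at log2 changes of -4.68 and -4.59.

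Contractile genes other than actin and Myh3 did not pass the threshold. The 4 adult myosin heavy chains had log2 changes of 0.01 (SE 0.26) for Myh7 of slow fibres, -0.55 (SE 0.22) for Myh2, -1.17 (SE 0.42) for Myh1 and -0.02 (SE 0.80) for Myh4 of fast fibres, with no stable sign for Myh7 and Myh4, which turned in 6 and 3 of 19 alternatives. Over the alternatives Myh2 ranged from -0.77 to -0.40 and Myh1 from -1.62 to -0.77. None of 16 slow fibre genes passed over all genes, and 1, the slow troponin subunit Tnni1 (log2 0.91, SE 0.21), was higher when adjusted over the list alone. Genes called only in this way, here and below, had limma adjusted p-values over all genes from 0.142 (Ncam1) to 0.339 (Ankrd1). The slow fibre list did not stand apart (camera, adjusted p = 0.137), and Lgals1 (0.48), Pln (-0.34) and Casq2 (0.33) were its next members by p. With 1 array left out these came as near to 0 as 0.30, -0.21 and 0.15. Of 18 fast fibre genes none passed, nor any adjusted over the list alone (camera, adjusted p = 0.149), with -0.27 for the fast troponin Tnnt3. Tnnt3 ranged from -0.42 to -0.15 with 1 array left out. Among 9 cardiac and developmental sarcomere genes Myh3 rose, and adjusted over the list alone Myl4, the atrial and embryonic light chain (log2 0.91, SE 0.20), and the stress-responsive Ankrd1 (1.25, SE 0.34, and 0.70 with modelled background) were higher and H19, an imprinted RNA (-0.58, SE 0.16), was lower. The adjusted camera p of that list was 0.0607. None of 30 thin filament and Z-disc genes passed, nor any adjusted over the list alone (camera, adjusted p = 0.478), with -0.72 for the giant spring protein Ttn and 0.45 for Lmod2. None of 17 target genes of the actin-regulated factors SRF and MRTF passed, nor any adjusted over the list alone (camera, adjusted p = 0.411). Their leading members were Ankrd1, Tagln2 (0.62) and Egr1, whose log2 change of -1.37 (SE 0.61) became -2.21 with an adjusted p of 0.0382 without wild-type array 2.

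Of 13 myogenic and satellite cell genes Myh3 rose, and the cell adhesion gene Ncam1 (log2 1.16, SE 0.21) was also higher when adjusted over the list alone (camera, adjusted p = 0.512). Of 13 neuromuscular junction and denervation genes none passed over all genes, while Ncam1 and the acetylcholine receptor subunit Chrnb1 (0.84, SE 0.17) were higher when adjusted over the list alone (camera, adjusted p = 0.199). With modelled background the changes of Ncam1 and Chrnb1 were 0.31 and 0.41. Fatty acid oxidation genes lay lower as a group (camera, adjusted p = 2.71e-04), with 21 of 24 members lower, a median of -0.20 and Slc25a20 as the 1 member that fell, also when adjusted over the list alone. With an estimated correlation the fatty acid oxidation list had an adjusted p of 0.465. Adipocyte markers lay lower in the same muscles, with a median of -0.54 and 9 of 10 members lower (camera with an estimated correlation, adjusted p = 0.626). No gene belongs to both lists, but that does not show that the 2 falls are separate. Acsl1, which activates long-chain fatty acids (-1.01, SE 0.35), and the dehydrogenases Acadm (-0.34) and Hadh (-0.69) did not pass. Without cardiac actin array 1 the values of Acsl1 and Hadh were -0.61 and -0.33. None of 41 oxidative phosphorylation and citric acid cycle genes passed, nor any adjusted over the list alone (camera, adjusted p = 0.149), and their median was -0.07. Among 22 glycolysis and glycogen genes none passed over all genes, and Gpd1, glycerol-3-phosphate dehydrogenase (-0.76, SE 0.15), was lower when adjusted over the list alone (camera, adjusted p = 0.137).

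The lists of calcium handling and excitation genes (23 members, camera adjusted p = 0.301), of atrophy, autophagy and growth control genes (24 members, 0.752), of heat shock and chaperone genes (18 members, 0.0542) and of extracellular matrix genes (25 members, 0.123) held no member past the threshold, nor any adjusted over the list alone. Their members of lowest p were Cacna1s, the voltage sensor of excitation (log2 -0.67, SE 0.18), Igfbp5 (-0.66, SE 0.19) and the ubiquitin ligase Fbxo32 (-0.69, SE 0.21), the small heat shock protein Hspb7 (0.90, SE 0.39), and Bgn, biglycan (0.65, SE 0.21). Hspb7 ranged from 0.40 without wild-type array 3 to 1.33 without wild-type array 2, and Bgn was 0.27 with modelled background. Timp1, a metalloproteinase inhibitor in the matrix list, had a log2 change of 1.43 (SE 0.64) that became 2.35 with an adjusted p of 7.09e-04 without the cardiac actin 1 array. Of 7 circadian clock genes none passed over all genes, and Nr1d1 (-0.57, SE 0.15, and -0.13 with modelled background) was lower when adjusted over the list alone. The clock list had a median of 0.12, a mean of -0.10 and a camera direction down (adjusted p = 0.614). The atrophy list likewise had a median of 0.02 and a mean of 0.05 with a camera direction down.

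Markers of other cell types moved in both directions, although no marker passed over all genes. Macrophage and leukocyte markers lay higher in cardiac actin soleus (camera, adjusted p = 1.78e-08), with 16 of 17 members higher and a median of 0.67. Its adjusted p was 0.465 with an estimated correlation, and its median was 0.40 without the cardiac actin 3 array. Cd74, the invariant chain (log2 0.77, SE 0.16, and 0.34 with modelled background), and the Fc receptor Fcgr3 (1.42, SE 0.31) were higher when adjusted over the list alone, and the complement gene C1qb (0.68) and Laptm5 (0.71) followed. The lowest values over the alternatives were 0.41 for C1qb and 0.44 for Laptm5. Adipocyte markers lay lower (camera, adjusted p = 0.00875), with 9 of 10 members lower and a median of -0.54, and had an adjusted p = 0.626 with an estimated correlation. Among them were the adipokines Cfd (-0.81, SE 0.30) and Adipoq (-1.08, SE 0.47), which was -0.63 without wild-type array 2 and -0.61 without cardiac actin array 1. The 1 member that was higher, Cidea (0.50, SE 0.19), had a lower unadjusted p than Adipoq (limma, 0.0262 against 0.0481). Cidea ranged from 0.32 to 0.61 over the alternatives. The brightest member, Car3, changed by -0.10 (SE 0.14). Smooth muscle and pericyte markers lay lower as well (camera, adjusted p = 0.00875), with all 8 members lower and a median of -0.26, led by Kcnj8 (-0.65, SE 0.22) and Rgs5 (-1.20, SE 0.43). That list had an adjusted p = 0.465 with an estimated correlation, and Rgs5 was -0.70 without cardiac actin array 1 and -0.66 with chip position in the model. The adipocyte list had an adjusted p of 0.0596 without wild-type array 2 and 0.0567 without cardiac actin array 1, and the smooth muscle list 0.0779 without wild-type array 1. The fibroblast and tendon markers did not pass as a list (camera, adjusted p = 0.0693), and 2 of 13, the tendon and matrix genes Fmod (-0.96, SE 0.23, and -0.24 with modelled background) and Kera (-1.45, SE 0.37), were lower when adjusted over the list alone. Endothelial markers (11 members, camera adjusted p = 0.149, Esam -0.29), Schwann cell and nerve markers (9 members, 0.301, Mbp -0.53), red blood cell markers (5 members, 0.254, Slc4a1 -0.59, and -0.04 without wild-type array 1) and genes of neighbouring fast muscle (12 members, 0.301, Fbp2 -0.52) held no member past the threshold, nor any adjusted over the list alone. All 12 of the last list's members also belong to other lists, and Fbp2 ranged from -0.85 to -0.21 with 1 array left out.

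**Figure D3:**
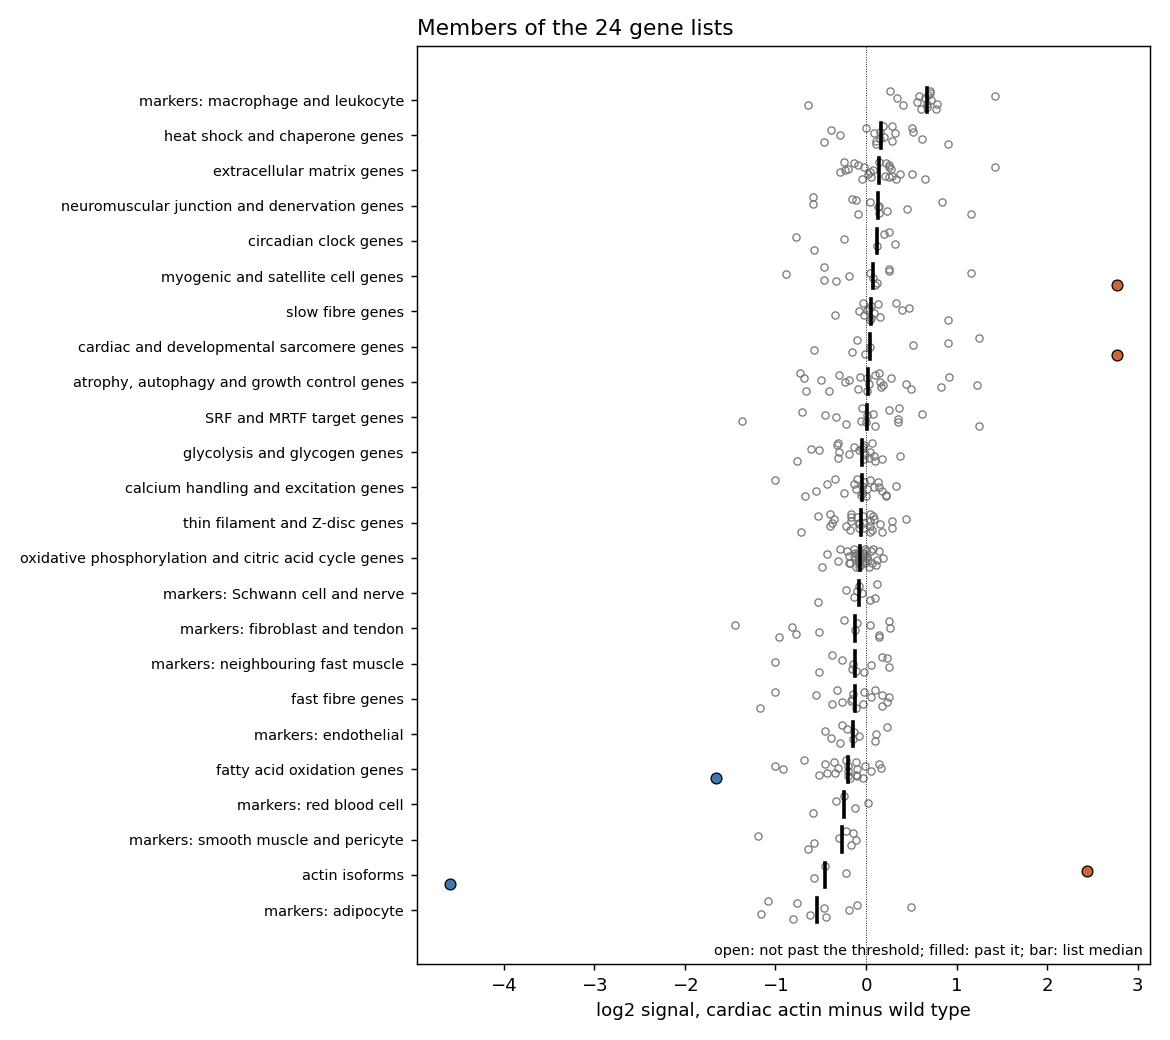
Log2 difference between cardiac actin and wild-type soleus for each tested member of the 24 gene lists, 1 list per line, with the list median as a black bar, members past the threshold filled and the others open. The macrophage and leukocyte median is 0.67, the adipocyte median -0.54 and the smooth muscle and pericyte median -0.26.

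The position of the changed genes was compared with the targeted gene, because a knockout line can keep chromosome of another strain around it. Of 169 tested genes within 20 Mb of Acta1 and 154 within 20 Mb of Actc1, 1 each passed the threshold, Acta1 and Actc1 themselves. With these exchanged genes left out, a count chosen after the result was seen, 0 of 168 genes near Acta1 passed, against 11 of 9166 elsewhere (Fisher's exact test, two-sided, odds ratio 95% interval 0 to 21.9, p = 1). Near Actc1 it was 0 of 153, against 11 of 9181 (interval 0 to 24.1, Fisher's exact test, p = 1). With so few changed genes these counts leave wide intervals.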

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

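The model of background from detection p-values (neqc) and median scaling over all rows were chosen after the data were seen. The other alternatives were fixed before. The neqc model was fitted to intensities already background-subtracted, and the detection score it rests on did not follow signal strictly. Hspb1, for example, was detected on 1 of the 3 cardiac actin arrays at a mean intensity of 7589. Whether the small changes of dim genes under neqc are nearer the truth was not tested. Quantile normalization without background correction was not run, because the deposited intensities were already background-subtracted, and the authors' value table could be used only for a count of probes. Of 1937 values of named genes other than Acta1 and Actc1 under the alternatives, 1809 kept their direction and side of the threshold, 114 lost the call, 2 gained it and 12 changed sign. Only genes called in the main processing could lose a call, and most named genes were not called there. The share of 114 in 1937 therefore understates how often calls were lost. Among the called genes other than Acta1 and Actc1, the calls kept ranged from 4 of 19 for Slc40a1 to 19 of 19 for Opn1mw. Acta1 was called in 19 of 19 alternatives, and Actc1 lost its call in 9 of 19. The main count was 18 genes and 18 rows. An offset of 50 gave 11 genes and 9 rows, detection on all 6 arrays 9 and 9, position on the chip 11 and 11, neqc 2 and 2, and median scaling over all rows 5 and 5. A test against a log2 change of 0.5 gave 7 genes, and of the 46632 probes in the authors' own values 3 probes passed, 1 up and 2 down. Leaving out 1 array gave 5 to 29 genes and 5 to 29 rows. The highest count came without the cardiac actin 1 array, with 14 of the 18 genes shared, and the other 5 left-out arrays gave at most 9. The cause of these differences was not tested. Of the other settings, median scaling over rows detected on all arrays gave 6 rises and 9 falls and cyclic loess 8 and 9. The median change over all genes stayed within 0.01 of 0 in each setting that gave one.

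Actc1 kept its direction but not its call with an offset of 50 (2.40), chip position (2.09), neqc (2.87) and median scaling over all rows (2.47), and ranged from 2.09 to 2.63 with 1 array left out, where only the set without cardiac actin 1 kept the call. Around Actc1, 0 genes passed in each setting that lost Actc1 itself. Acta1 ranged from -4.86 to -4.46. The sign of Myh7 turned with array weights (-0.044) and chip position (-0.30), and its values ranged from -0.17 to 0.30 with 1 array left out (-0.07, -0.09, -0.17 and -0.10 below 0). Myh4 became 0.24 with chip position and ranged from -0.70 to 0.78 with 1 array left out, where it also took 0.73. With 1 array left out Gpihbp1 ranged from -0.56 to 0.034, Hbb-b2 from -0.62 to 0.0017 and Alas2 from -0.67 to 0.16, with values below 0 in all other settings, and none of these genes passed in any setting.

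The actin list lost its call, at adjusted camera p-values of 0.0609 with median scaling, 0.0515 with detection p under 0.01, 0.0510 with the replicate block, 0.0717 with neqc and 0.0505 with the mean of a gene's rows. The heat shock list gained one with median scaling (0.0135), an offset of 50 (0.0426), no filter (0.0275), array weights (0.0466), the replicate block (0.0328) and median scaling over all rows (0.0181). Without a filter the endothelial (0.0236) and fibroblast lists (0.0298) passed, and with array weights the fast fibre, glycolysis and fibroblast lists (each 0.0466). With chip position the fast fibre, glycolysis and endothelial lists (each 0.0106) and the fibroblast list (0.0237) passed, and with median scaling over all rows the slow fibre (0.0371), cardiac and developmental (0.0160) and fibroblast lists (0.0189). With 1 array left out the adjusted camera p ranged from 0.00685 to 0.140 for actins, 0.0476 to 0.689 for slow fibre, 0.00161 to 0.900 for fast fibre, 0.00997 to 0.113 for cardiac and developmental, 0.00668 to 0.677 for oxidative phosphorylation, 0.00161 to 0.851 for glycolysis, 9.36e-04 to 0.395 for heat shock and 0.00965 to 0.502 for matrix genes. For marker lists it ranged from 2.29e-04 to 0.0596 for adipocytes, 0.0353 to 0.608 for endothelium, 0.00213 to 0.0779 for smooth muscle, 0.00355 to 0.226 for fibroblasts and 0.0426 to 0.711 for red blood cells. The macrophage list (1.98e-12 to 1.02e-04 with 1 array left out) and the fatty acid oxidation list (8.37e-05 to 0.0102) passed in all 19 alternatives by camera with the preset correlation. With an estimated correlation no list passed in any of them.

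The replicate number as a block gave 13 genes, 12 of them shared with the fit without it. The deviations of same-numbered arrays from their group means had correlations of -0.04, -0.29 and 0.09. Array 1 of wild type went best with cardiac actin array 2 (0.27). Deviations within a group cancel out, so these correlations depend on each other. With so few arrays they cannot tell whether same-numbered samples share more than a number, such as a batch. Between 33.6% and 37.9% of the rows were detected on an array, and the amounts added before the log2 step limit the changes of genes near background.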

Other observations

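The tests of marker lists against each other, of the left-out arrays for the macrophage list, of the foreign-sequence rows and of genes near Hprt, near Acta1 (unadjusted) and on the X chromosome were chosen after the results were seen; the counts over splits of the arrays were fixed before. The 6 arrays can be split into 3 and 3 in 10 ways, so no share of splits can fall under 0.05. The real split gave 18 rows and 18 genes, and the highest of the other splits gave 1 row and 1 gene, so that 1 of the 10 splits reached each real count. For lists past camera with the preset correlation the real split gave 5, the actins among them, and the highest of the others 7, and 6 of the 10 splits, the real one included, gave 5 or more. No split gave a list past the threshold with an estimated correlation.

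Fry also tests whether the members of a list change in either direction, a form that was not simulated. This form passed for the actin isoforms (fry, adjusted p = 1.20e-04), where the exchanged Acta1 and Actc1 set the result and the other 3 members did not pass. It also passed for the cardiac and developmental sarcomere genes (0.00192), the myogenic and satellite cell genes (0.00837), the fatty acid oxidation genes (0.0222) and the neuromuscular junction and denervation genes (0.0243). Fry's test for a shift in one direction, the form that was simulated, passed for no list, with the smallest adjusted p at 0.125. Some of these lists share members, since Myh3 and Ncam1 each belong to 2 of them. Myh3 was the 1 member past the threshold over all genes in the cardiac and developmental and the myogenic lists, and Slc25a20 in the fatty acid oxidation list. How far these single genes set the fry results was not tested.

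Rows for β-galactosidase and Hprt were both higher in cardiac actin muscle, with intensities of 1555, 9014 and 10190 against 36.5, 3.3 and 15.4 for β-galactosidase. Unspecific brightness of rows for foreign sequences is argued against by the other 10 such rows, whose median log2 change was -0.027 and whose highest was 0.27. A stretch of X chromosome from another strain around Hprt stays open: 4 of 67 genes within 20 Mb passed an unadjusted p of 0.05, against 785 of 9268 elsewhere (Fisher's exact test, two-sided, odds ratio 0.686, p = 0.658, adjusted p = 0.854 over 4 position tests). The Hprt window was not tested at the lower thresholds used near Acta1 (0.01) and on the X chromosome (0.01 and 0.001). Few strong changes near Hprt could therefore be missed by this count. A candidate explanation is that reporter and selection sequences carried by the modified alleles add to both rows, which was not tested because neither the constructs nor the probe sequences are given in the sources used here. The row for the neomycin resistance gene changed by -0.01 and was detected on no array.

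Macrophage markers were higher while adipocyte and smooth muscle markers were lower by camera with the preset correlation. With an estimated correlation none of these lists passed (camera, adjusted p = 0.465, 0.626 and 0.465). A lower share of fibre RNA alone would raise all of them, but the macrophage median lay 1.21 above the adipocyte median and 0.93 above the smooth muscle median. The permutation tests over members (p = 8.80e-04 and p = 0.00432) add little to this. The lists were compared because they had moved apart, and genes of a list are not independent of each other. A lower share together with other differences in cell content was not excluded. A single array as the source stays open: the macrophage median was lowest, at 0.40, without the cardiac actin 3 array, and on the 5 arrays left an exact permutation test cannot give a p under 0.1. Variation between pools that does not follow genotype could not be told apart from genotype: 1 of the 10 splits, the real one, gave a camera p as small (7.41e-10, against 2.25e-07 in the nearest other), and no share under 0.05 is possible. More leukocyte RNA with the cardiac actin genotype remains a hypothesis; the brightest members were Laptm5 (mean intensity 835 to 1577), H2-Aa (891 to 1371) and Ctss (734 to 1782), with log2 changes of 0.71 (SE 0.25), 0.59 (SE 0.35) and 0.78 (SE 0.50), no member belongs to another list, and 2 of the 8 smooth muscle members are also in the actin list.

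Among tested genes on the X chromosome, Opn1mw and Hprt passed the threshold, and Igsf1 (1.33), Atp1b4 (1.09), Tceal7 (1.09) and Tceal5 (0.93), picked after their values were seen, had unadjusted p-values from 1.83e-04 to 3.69e-04. An X chromosome of another strain may lie behind them, but 8 of 307 X-linked genes passed an unadjusted p of 0.01 against 229 of 9029 others (Fisher's exact test, odds ratio 1.03, p = 0.854), while at 0.001 the counts were 6 and 42 (odds ratio 4.26, adjusted p = 0.0185), a threshold that follows the genes first noticed. Chromosome of another strain kept around Acta1 could add calls there: 9 of 168 genes within 20 Mb, Acta1 left out, passed an unadjusted p of 0.01 against 227 of 9167 elsewhere (Fisher's exact test, odds ratio 2.23, 95% interval 0.988 to 4.41, p = 0.0397, adjusted p = 0.0794 over the 4 position tests). Agrp (1.67), Arv1 (-0.65) and Rnf166 (-0.89), also picked after their values were seen, led that group. The adjustment over these 4 tests was itself chosen after the unadjusted p of 0.0397 was seen (Fisher's exact test), which alone would have counted for this explanation. Neither explanation is settled. The labels give both genotypes one strain designation, CBB6F1xFVB/n, but it is written as a cross. It does not show that both genotypes carry the same chromosomes and does not count against either explanation.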
